A study of Mus musculus with 217 samples.

How the data were processed

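Bulk RNA was measured in 217 libraries of 1 mm punches of 3 striatal subregions of C57BL/6J mice aged about 10 weeks: nucleus accumbens (NAc, 77 libraries), dorsomedial striatum (DMS, 70) and dorsolateral striatum (DLS, 70). Per the labels' protocols, mice lived under 12 h of light and 12 h of dark and were killed at 6 times given in hours after lights on (Zeitgeber time, ZT): ZT2, ZT6, ZT10, ZT14, ZT18 and ZT22. Stranded total RNA libraries for ultra-low input were sequenced on an Illumina NextSeq as paired reads of 75 bp, with 40 M reads targeted per library.

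Per the submitters' processing notes, reads were trimmed with Trimmomatic after FastQC, aligned with HISAT2 2.1.0 to the Ensembl GRCm38 genome and counted per gene with HTSeq 0.10.0 in union mode. Genes were filtered on their share of counts in each region, and counts were normalised by the authors with DESeq2. The notes also list a human build (GRCh38) for these samples, which contradicts the mouse labels and the mouse gene identifiers of the tables. Whether the counting used the strand is not stated, so reads of genes that overlap on opposite strands, and of paralogs and pseudogenes, are uncertain. The deposited values are log2 of DESeq2-normalised counts, made by the authors for each region separately, so a level in 1 region's table is not on a common scale with another's. In DMS and DLS each value is log2 of the normalised count plus 1: a median of 99.9% of the values of a library were whole reads times that library's own step (tolerance 0.01 reads). In NAc a median of only 2.01% were, and 9 values lay below 0. The NAc means of animals numbered up to 29 and from 31 were also closer than sampling allows (SD of the t statistics 0.37 over 11867 genes). A further adjustment was therefore made to the NAc values that no label records, and the depth of the NAc libraries is unknown.

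The tables hold 11867 genes in NAc, 12101 in DMS and 11394 in DLS (the labels state 11395 for DLS), of which 11842, 12073 and 11371 were matched by identifier to a symbol and coordinates in GENCODE release M21 (GRCm38). The 11283 genes in all 3 tables were used to compare regions. No filter was added. Reads recovered from the whole-read steps summed to between 35711640 and 57468484 per DMS library and between 29719087 and 56799764 per DLS library over the listed genes. Outside the 3 most abundant genes of each library, which are mostly ribosomal RNA, the sums were 14.6 to 40.1 and 5.51 to 35.6 M reads. Sequencing reads without molecular identifiers are not independent molecules, so no counting interval is given, and the errors printed are those between libraries.

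Daily rhythm was tested in limma 3.58.1 (R 4.3.3, tables read with version 1.17.8 of the data.table package) with a cosine and a sine of 24 h (2 degrees of freedom), a sex term and a variance trend. The amplitude is the height of the fitted peak above its mean on the log2 scale, the fold is from trough to peak, and an adjusted p (Benjamini-Hochberg) of less than 0.05 made a gene rhythmic. The rhythm of each sex and the difference of rhythm between the sexes (2 degrees of freedom) came from fits with separate terms for the sexes, and the sex difference of level from a fit with time as 6 levels. The difference of rhythm between regions was tested in a joint limma fit with the animal as a block (estimated correlation 0.039). The mean amplitude of 20 core clock and clock output genes was compared between regions by swapping the region labels within animals that had both regions (two-sided permutation test, 10000 resamples, smallest p 1e-04). Intervals of peak-time differences are 95% bootstrap intervals over 100 draws of animals. Of 33 gene lists fixed beforehand, those with measured genes were tested. Rhythmic members were compared with all other genes by Fisher's exact test (two-sided). Dark minus light and male minus female values were compared by camera with a preset correlation of 0.01. Fisher's exact test takes genes as independent, but members of a list can vary together between libraries. Its p values can therefore be too small. Tables were handled and plots drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

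Libraries were grouped by the region, sex and time of their labels. The labels name the animal of each library, which pairs libraries of 1 animal across regions: 47 animals gave 3 regions, 30 gave 2 and 16 gave 1. Residual correlation between regions of 1 animal had a median of 0.05 in 63 animals (NAc and DMS), 0.02 in 57 (NAc and DLS) and 0.11 in 51 (DMS and DLS). Males and females are numbered separately, and a male and a female of the same number had median correlations of -0.02, -0.05 and 0.05 in NAc, DMS and DLS after the range of numbers and the DMS class were removed. Without that removal a block for the number had an estimated correlation of -0.024, 0.225 and 0.148 for rhythm and -0.02, 0.197 and 0.148 for the sex difference of level. Most of these pairs shared a time (23 of 26, 23 of 25 and 21 of 24), so the numbers are not read as pairs, and a block for the number is an alternative.

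After the data were seen, a term was added for DMS: libraries fell into a class with a low and a class with a high share of mitochondrial rRNA, and DMS results are given with and without a term for this class. Also added were the mitochondrial rRNA share as a covariate, voom on the recovered DMS and DLS reads, and fits of each pair of regions alone with a weight per region. The joint fit assumes 1 spread for all regions, but the median residual SD was 0.31 in NAc, 0.22 in DMS and 0.20 in DLS (log2). In data simulated without any difference and with these unequal spreads, the joint fit gave 789, 652 and 196 genes an unadjusted p under 0.05 for NAc and DMS, NAc and DLS, and DMS and DLS, where 564 of 11283 are due; the pair fits gave 517, 541 and 569.

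Genes named in the text follow a rule fixed beforehand. For rhythm these are every measured core clock and clock output gene, the 6 other rhythmic genes of largest amplitude per region (mean log2 of at least 6, peaks of the sexes within 4 h), and up to 3 genes of smallest p from each other list. For sex these are every measured gene of the X- and Y-linked lists (Y-linked genes are not analysed here), the 5 genes of largest fold in each direction (same direction at 5 or more of 6 times) and up to 3 genes of each other list. For region differences these are the 5 genes of smallest p, and 3 genes per region would have been named for the sex difference of rhythm had any passed. Region markers are given as levels without a test. Genes outside the rule are said to be so.

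Alternatives tried were quantile normalisation, libraries scaled to an equal sum, a pseudocount of 8, a mean log2 of at least 6, a term for the range of animal numbers, other thresholds, robust and weighted fits, time as 6 levels, each sex fitted alone, each time left out, each library left out, blocks for numbers and animals, and an estimated correlation per gene list. The tests were tested on simulated data, random values with the mean and residual SD of each gene, in which added rhythms with an amplitude of 0.4 (log2) were recovered for 89.4% of genes in NAc, 93.9% in DMS and 100% in DLS, and amplitudes of 0.1 for 4.5%, 20.9% and 46.3%. In simulated data without a difference the swap test gave p under 0.05 in 2, 4 and 4 of 40 runs for the 3 pairs of regions. With a difference of 0.1 it did so in 40 of 40 runs each. So few runs leave the rate of false calls uncertain. The simulated noise was independent between genes and the swaps fewer, so noise shared by the clock genes of a library was not covered.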

Results

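The 3 subregions differ in their inputs and roles: NAc is the ventral, limbic part of the striatum, DMS is associated with goal-directed action and DLS with habits. The libraries cover 93 animals and 6 times of day, with 6 or 7 libraries per sex and time in NAc and 5 or 6 in DMS and DLS. NAc had 37 female and 40 male libraries, DMS 34 and 36, and DLS 35 and 35. The median depth over listed genes was 44189905 reads in DMS and 42884873 in DLS, and unknown in NAc. The labels of sex matched the level of Xist, the RNA that silences the inactive X chromosome, in every library: the highest male value was 9.90, 9.60 and 9.76 (log2) in NAc, DMS and DLS, and the lowest female value 10.89, 11.68 and 10.80. The male medians were 5.60, 5.73 and 4.62, so the highest male libraries lay well above a typical male. The cause was not tested. Known markers of striatal position were graded between the tables, which were normalised separately and so were not tested. Crym, a ventral marker, averaged 12.72 ± 0.34 (log2, SD, n = 77) in NAc, 11.53 ± 0.35 (n = 70) in DMS and 10.47 ± 0.44 (n = 70) in DLS, and Wfs1, Peg10, Nts and Zcchc12 followed the same order. Cnr1, the cannabinoid receptor gene of the lateral striatum, averaged 11.25 ± 0.40, 12.82 ± 0.33 and 13.82 ± 0.22, and Gpr155 followed it.

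Mitochondrial ribosomal RNA took a large and variable share of the normalised counts, with a median of 35.01% in NAc (22.7 to 50.5%), 27.8% in DMS (19.02 to 52.6%) and 41.6% in DLS (13.2 to 53.03%). In NAc the libraries of lowest share (22.69 to 25.13%) were all female. In DMS the libraries fell into a low class of 37 (19.02 to 29.9%) and a high class of 33 (35.3 to 52.6%). The labels do not name the classes, but these nearly follow the animal numbers: all 26 libraries of animals numbered 31 or higher were of the high class, and 37 of 44 of lower numbers of the low class. The 7 libraries of lower numbers in the high class were all male (numbers 15 and 24 to 29). Class and sex are therefore entangled within the lower numbers. The first principal component of the DMS values held 45.2% of the variance and parted the classes with 0 libraries on the wrong side, and 9503 of 12101 genes (78.5%) differed between them. The high class held 17 females and 16 males but was spread unevenly over the day, with 3 of 12 libraries at ZT2, 4 of 12 at ZT6, 7 of 11 at ZT10, 7 of 11 at ZT14, 10 of 12 at ZT18 and 2 of 12 at ZT22. Class and time of day are therefore partly entangled in DMS, and the main DMS results are given also with a term for the class.

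**Figure D1:**
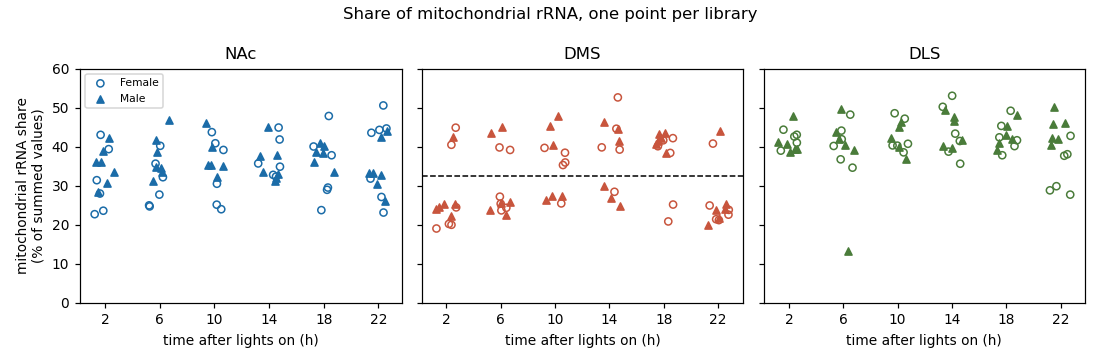
Share of normalised counts from mitochondrial ribosomal RNA (percent) in each library by time of day (ZT, h), in NAc, DMS and DLS, with females and males as separate symbols. The dashed line in DMS lies between the highest library of the low class (29.9%) and the lowest of the high class (35.3%).

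The first question was which transcripts follow the time of day in each subregion. The core clock, a feedback loop of transcription factors, cycled in all 3. Ciart, a repressor of the loop (ENSMUSG00000038550, chromosome 3, 95878503 to 95882251, minus strand), peaked near lights off: its amplitude was 0.75 ± 0.07 (log2, SE, n = 77) in NAc, 0.98 ± 0.05 (n = 70) in DMS and 1.23 ± 0.05 (n = 70) in DLS, or 2.84, 3.91 and 5.54-fold from trough to peak (adjusted p 1.17e-12, 1.8e-24 and 1.85e-30). Arntl, which drives the loop (chromosome 7, 113207465 to 113314126), peaked about lights on at 23.9, 23.5 and 23.5 h, with folds of 1.69, 1.95 and 2.02 (adjusted p 6.25e-10, 3.47e-15 and 1.7e-16). Per2, an arm of the loop that also responds to light and hormones (chromosome 1, 91415982 to 91459324), peaked at 15.6, 17.01 and 15.7 h with folds of 1.90, 2.05 and 3.19 (adjusted p 0.000553, 1.13e-07 and 4.37e-17). Nr1d1 peaked before lights off at 8.96, 9.37 and 9.45 h (folds 2.06, 2.37 and 2.91). The output gene Dbp (chromosome 7, 45705088 to 45710203) peaked at 11.9, 11.8 and 12.2 h (folds 1.82, 2.34 and 2.54).

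**Figure D2:**
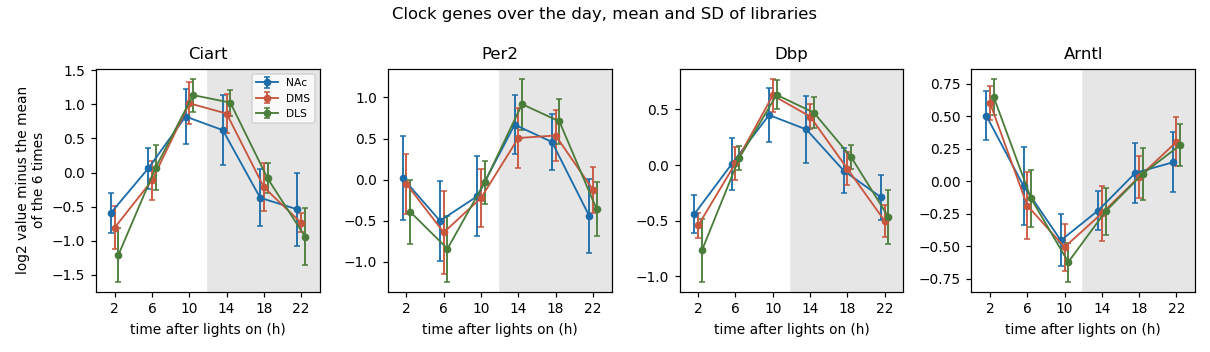
Ciart, Per2, Dbp and Arntl by time of day (ZT, h) in NAc, DMS and DLS, as log2 values minus the mean of the 6 times; points are means of the libraries at a time and bars their SD, and the dark phase is shaded. Ciart and Dbp peak near lights off, Per2 after it and Arntl about lights on, and the curves of DLS span the widest range.

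With the class term the DMS clock changed little: Ciart kept an amplitude of 0.95, Nr1d1 0.63, Dbp 0.61 and Arntl 0.51, and Per2 had 0.63 in place of 0.52 (adjusted p 1.49e-12). Of 12 core clock genes 10 were rhythmic in DMS and in DLS and 5 in NAc (8 in NAc adjusted over the list alone), and of the clock output genes 9 of 9 in DMS, 8 of 8 in DLS and 6 of 9 in NAc (7 adjusted over the list alone). The other members of the loop past the threshold in all 3 regions were Cry1 (folds 1.49, 1.58 and 1.94, peaks at 18.9, 18.6 and 19.5 h) and Nr1d2, and among outputs Tef, Hlf, Bhlhe40 and Bhlhe41. In NAc the amplitudes of Per1 (0.20 ± 0.06, adjusted p 0.103), Per3 (0.23 ± 0.06, 0.0632), Usp2, Clock, Npas2, Cry2, Nfil3 and Wee1 did not pass. Rora and Rorb passed in no region, with folds of at most 1.10.

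In NAc 304 of 11867 genes (2.6%) were rhythmic, 173 of them (56.9%) with a peak in the dark. The largest amplitudes outside the clock belonged to Rbm3, an RNA-binding protein induced by cold (ENSMUSG00000031167, X chromosome, 8138975 to 8145880), at 0.64 ± 0.06 (log2, SE, n = 77; 2.42-fold, peak 12.3 h, adjusted p 8.05e-13), and to the matrix gene Papln (2.26-fold, peak 7.29 h, 5.14e-05). Hspb1, a small heat shock protein, followed (2.23-fold, peak 19.3 h, 0.0133), then the proton channel Hvcn1 (2.09-fold, 3.23 h, 0.008), the calcium pump Atp2a3 (2.07-fold, 2.96 h, 0.000199) and Zbtb16, a target of glucocorticoids (2.01-fold, 14.2 h, 0.00775). Chaperones of the endoplasmic reticulum (ER), which fold secreted proteins, had the smallest p of the lists for rhythmic members: 12 of 21 (14 adjusted over the list alone) against 2.5% of other genes (adjusted p 4.93e-13, Fisher's exact test). Hspa5 (chromosome 2, 34771970 to 34777547) peaked in the dark at 18.9 h with a fold of 1.59 (adjusted p 2e-06), Pdia4 at 19.1 h (1.42-fold) and Calr at 20.8 h (1.35-fold). Cytosolic heat shock chaperones followed with 8 of 18 (12 over the list alone; 9.48e-08), among them Hspa8 (1.38-fold, peak 21.2 h), Chordc1 (1.46-fold) and Dnajb1 (1.38-fold).

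Lists with a larger share of rhythmic members than other genes in NAc were also clock output (adjusted p 2.26e-07, Fisher's exact test, which takes genes as independent), glucocorticoid-responsive genes (6 of 16, 10 over the list alone, 1.39e-05), core clock (4.67e-05), endothelial and mural markers (5 of 15, 0.000138) and the pair of cold-inducible genes (2 of 2, 0.00299). Tsc22d3, a glucocorticoid target, peaked at 14.0 h (1.72-fold, adjusted p 8.25e-07) and Sgk1 at 12.4 h (1.48-fold); Cirbp, the other cold-inducible gene, peaked at 9.73 h (1.75-fold); and the tight-junction gene Cldn5 at 22.4 h (1.83-fold, 8.77e-08). No member of the lists of medium spiny neuron, indirect-pathway, interneuron, opioid, dopamine, glutamate receptor, cholesterol synthesis, oxidative phosphorylation or ribosomal protein genes was rhythmic in NAc in limma. With 2.6% of other genes rhythmic, none of these lists differed from them (adjusted p 0.719 or more, Fisher's exact test). In camera, which compares a list with all other genes, ER chaperones (adjusted p 2.12e-17) and heat shock chaperones (6.15e-13) were higher in the dark, and both held with an estimated correlation (0.000151 and 0.00178). Ribosomal proteins (5.29e-14), oxidative phosphorylation (1.89e-13) and immediate early genes (0.00188) did not, with adjusted p 0.516 each. Among the 10 lists past the threshold this left 2.

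In DLS 2392 of 11394 genes (21%) were rhythmic, 52.1% with a peak in the dark. The median fold was 1.19, and 119 genes exceeded 1.5-fold. Scaled to an equal sum, the libraries gave 216 rhythmic genes in DLS and 108 in NAc. That scaling moves every value of DLS male ZT6 number 13 by -2.43 (log2). In this library the rRNA-like genes Gm42418 and Gm26917 held 68.4%, and no equal-sum fit without it was run. Ano2, a calcium-activated chloride channel (ENSMUSG00000038115, chromosome 6, 125690419 to 126040126), had the largest amplitude outside the clock at 0.94 ± 0.05 (log2, SE, n = 70; 3.68-fold, peak 11.5 h, adjusted p 1.53e-26). The potassium channel gene Kcna5, also on chromosome 6 (126532551 to 126535412), had 2.17-fold (peak 12.7 h, 2.21e-14). Rbm3 and Zbtb16 had 2.33-fold each (peaks 12.7 and 13.8 h), the axon guidance gene Ntng1 2.09-fold (0.508 h) and Xdh, of purine breakdown, 2.05-fold (14.2 h). Heat shock chaperones were rhythmic in 16 of 18 (18 over the list alone; adjusted p 4.32e-08, Fisher's exact test), with Hspa8 at 1.43-fold (peak 22.7 h), Ahsa1 at 1.35-fold and Hsph1 at 1.44-fold. ER chaperones were rhythmic in 15 of 21 (17 over the list alone; 1.54e-05), with Hsp90b1, Dnajb11 and Manf at folds of 1.29, 1.28 and 1.31. Clock output (3.99e-05), core clock (5.67e-05), endothelial and mural markers (9 of 16; 0.0135), neuropeptides (5 of 7; 0.031) and glucocorticoid-responsive genes (8 of 16, 11 over the list alone; 0.0432) also passed.

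Genes of striatal neurons cycled with small amplitudes in DLS. Tac1, the peptide of direct-pathway neurons, had 1.25-fold (peak 18.0 h, adjusted p 3.62e-05), Penk, the peptide of indirect-pathway neurons, 1.16-fold (23.3 h, 0.0203), Pdyn 1.25-fold (4.98 h, 0.0259) and the signalling gene Ppp1r1b 1.19-fold (13.9 h, 0.00689). The largest of the receptors was Gabra2, of the GABA-A receptor, with 1.52-fold (22.6 h, 1.49e-12), and among glutamate receptors Grik5 and Grm8 had 1.40-fold each. The other lists did not differ from all other genes in rhythmic members in DLS (adjusted p 0.0804 or more). These were medium spiny neuron genes (9 of 20), direct-pathway (4 of 9) and indirect-pathway (2 of 8) genes, opioid genes (4 of 6), dopamine signalling (5 of 12), GABA (4 of 18) and glutamate receptors (6 of 22), interneuron markers (3 of 10), striatal region markers (5 of 11), immediate early genes (5 of 22), cold-inducible genes (2 of 2) and cholesterol synthesis (7 of 23). They were also oxidative phosphorylation (9 of 75), mitochondrially encoded genes (0 of 13), ribosomal proteins (14 of 77, 6 over the list alone), collagen and matrix (3 of 8), hormone-related (3 of 7) and X-linked genes (3 of 7). Among cell markers they were astrocyte (2 of 15), oligodendrocyte (2 of 14), precursor (4 of 10), microglia (1 of 15), choroid plexus (1 of 1), cortical (0 of 6) and red blood cell markers (0 of 5). Camera placed 7 lists past the threshold for dark minus light in DLS, and 0 with an estimated correlation. Heat shock chaperones, core clock and clock output then had adjusted p 0.0775 each, and ER chaperones 0.189. At an unadjusted p under 0.05 limma gave 3956 rhythmic genes in DLS and 1791 in NAc.

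In DMS 6207 of 12101 genes (51.3%) were rhythmic without the class term and 3051 (25.2%) with it, 2549 of them the same genes. Inside the low class alone 948 genes passed, inside the high class 1811, and 384 in both, with a median peak difference of 1.31 h. Of the 6 genes of largest amplitude outside the clock, Angptl2, a secreted protein (chromosome 2, 33216069 to 33247717), had 2.65-fold (0.70 ± 0.14, SE, n = 70; peak 9.37 h, adjusted p 0.000278) and 2.99-fold with the class term (1.71e-05), and Tchh 3.21-fold and 1.48-fold (0.00795). The other 4 were lost with the class term: the proliferation gene Mki67 (4.25-fold, adjusted p 0.038 to 0.76), Gm10800 (3.42-fold, 0.000527 to 0.0812), E330034L11Rik (3.36-fold, 0.00627 to 0.289) and Ankrd11 (2.68-fold, 0.00861 to 0.973). Rbm3 (2.54-fold, 2.26 with the class term), Cirbp (1.99 and 1.98), Tsc22d3 (1.90 and 1.75), Sgk1 (1.81 and 1.67), Gabra2 (1.49 and 1.48) and the heat shock genes Hsph1 (1.51 and 1.49), Chordc1 (1.61 and 1.53) and Ahsa1 (1.39 and 1.38) changed little.

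Heat shock chaperones were rhythmic in 17 of 18 in DMS and 15 with the class term (adjusted p 0.00166 and 1.2e-05, Fisher's exact test), ER chaperones in 20 and 16 of 21 (0.00037 and 2.2e-05), clock output in 9 and 9 of 9 (0.0255 and 3.26e-05) and core clock in 10 and 10 of 12 (0.151 and 0.000258). Immediate early genes, induced by neuronal activity, were rhythmic in 12 of 22 (0.86) and in 16 with the class term (3.26e-05): Homer1 had 1.34-fold and 1.38-fold (peak 20.2 and 21.8 h) and Dusp6 1.52-fold and 1.57-fold. Other lists had fewer rhythmic members with the class term. Ribosomal proteins fell from 77 of 77 (1.22e-21) to 9, fewer than among other genes (0.024), nuclear oxidative phosphorylation from 54 of 75 (0.00233) to 6 (0.00132, again fewer), interneuron markers from 8 of 10 (0.321) to 0 (0.15) and mitochondrially encoded genes from 8 of 13 (0.86) to 0 (0.11), neither different from other genes in either fit. Oligodendrocyte markers had 8 of 14 in both fits (0.86 and 0.0433). For dark minus light, camera placed 8 lists past the threshold and 11 with the class term. Heat shock chaperones were higher in the dark (3.54e-14; with an estimated correlation 0.00102); immediate early genes (1.48e-09; 0.351) and ER chaperones (1.48e-09; 0.0924) lost the call with an estimated correlation. Ribosomal proteins were higher in the dark without the class term (adjusted p 0.014, with an estimated correlation 0.936) and lower with it (0.0128). Scaling libraries to an equal sum moves every dark minus light value by -0.08 in NAc, -0.11 in DMS and 0.05 in DLS (log2). The medians of the lists named here as higher in the dark keep their sign under it, except ribosomal proteins in DMS. In voom on the recovered reads 6146 DMS genes and 2451 DLS genes were rhythmic.

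**Figure D3:**
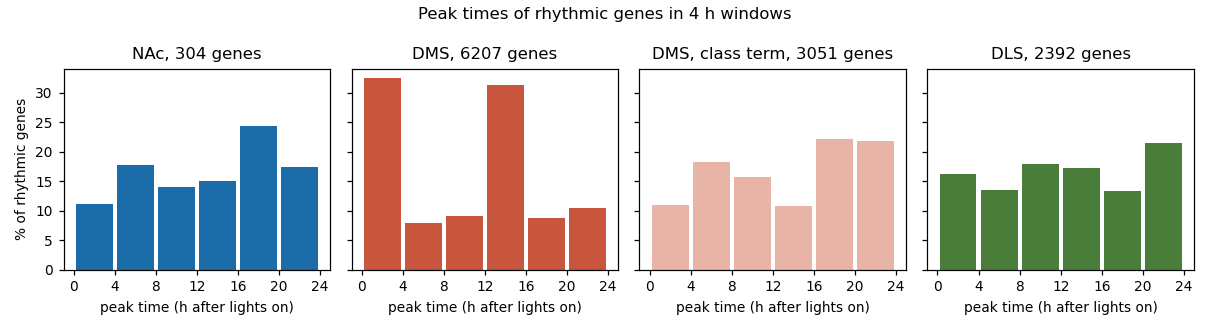
Percent of the rhythmic genes that peak in each 4 h window of the day in NAc, DMS, DMS with the class term, and DLS. Without the class term 32.5% of DMS genes peak from 0 to 4 h and 31.3% from 12 to 16 h; with it these windows hold 10.9% and 10.8%.

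The next question was whether rhythms differ between the sexes. Ciart cycled in females and males alike: in NAc its amplitude was 0.70 ± 0.10 (log2, SE, n = 37) and 0.82 ± 0.10 (n = 40), in DMS 1.02 ± 0.08 (n = 34) and 0.95 ± 0.07 (n = 36), and in DLS 1.21 ± 0.08 and 1.26 ± 0.08 (n = 35 each). In DMS it also passed in both sexes with the class term (limma adjusted p 6.07e-15 and 1.58e-15). Dbp, Arntl, Nr1d1 and Rbm3 passed in both sexes in each region, and Per2 in DMS and DLS. The 15 genes rhythmic in each sex in NAc, 621 in DMS and 337 in DLS had median peak differences between the sexes of 0.51, 1.30 and 1.13 h. In females 85, 2164 and 2028 genes passed in NAc, DMS and DLS, and in males 35, 1201 and 501; with the class term DMS had 1532 in females, 1529 in males and 575 in both. Which sex had more was not stable in DMS: a term for the range of animal numbers gave 1172 in females and 2961 in males, and leaving out single libraries gave 1323 to 4063 in females and 820 to 2063 in males. The range term does not remove the class difference of the 7 high-class libraries of lower numbers, all male. Its counts by sex are therefore entangled with the class. In NAc leaving out single libraries gave 65 to 120 in females and 18 to 46 in males. In DLS the excess in females shrank to 1308 against 730 in males when each sex was fitted alone. With the mitochondrial rRNA share as a covariate DLS had 1595 in females and 501 in males. DLS females number 2, 3 and 4, all at ZT22, had shares of 28.8, 27.7 and 29.86%. The other DLS females had 34.61% or more. Share and time are therefore partly entangled in DLS females. Tested directly in limma, no gene passed the threshold for a difference of rhythm between the sexes in any region. The count was also 0 in DMS with the class term and in voom for DMS and DLS. At an unadjusted p under 0.05 there were 475, 459 and 1284 of 11867, 12101 and 11394 genes, and 1144 in DMS with the class term. The counts in DLS and in DMS with the class term exceeded the share of 0.05 due by chance. Those in NAc and in DMS without the term did not. The lowest adjusted p was 0.743, 0.932, 0.248 and 0.0606. In simulated data the changed genes were given rhythms of equal amplitude and opposite phase in the sexes. Where the difference between these rhythms was 0.4 (log2), it was recovered for 43.9% of genes in NAc, 57.6% in DMS and 84.8% in DLS. A difference of 0.2 was recovered for 6%, 16.4% and 23.9%, so most differences of that size would be missed. With sex by time as 6 levels in place of the cosine, 13 genes passed in DLS, 0 in DMS and 1 in NAc, which, named after its values were seen, was Ephb6 (adjusted p 0.0176).

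Among the genes analysed, which leave out Y-linked genes, the largest sex difference of level in each region was that of the X-linked Xist. Xist (103460366 to 103483254) was 160-fold, 154-fold and 135-fold higher in females in NAc, DMS and DLS. Male Xist values spread from -0.63 to 9.90 in NAc, 0 to 9.60 in DMS and 0 to 9.76 in DLS (log2), so these folds are rough. Genes that escape X inactivation, and so are read from both female copies, followed at each of 6 times: Eif2s3x (94188707 to 94212862) had male minus female values of -0.62 ± 0.05 (log2, SE; 37 females, 40 males), -0.61 ± 0.06 (34 and 36) and -0.57 ± 0.03 (35 and 35), with adjusted p 2.85e-14, 3e-11 and 1.7e-23. Kdm6a, a histone demethylase (ENSMUSG00000037369, 18162575 to 18279936), had -0.43 ± 0.05, -0.41 ± 0.04 and -0.50 ± 0.04 (2.71e-09, 1.51e-13 and 8.23e-19), Ddx3x -0.35, -0.36 and -0.36, and Kdm5c -0.30, -0.31 and -0.26. The predicted gene Gm2223 on the X chromosome had -0.58, -0.63 and -0.55. Pbdc1 passed in DMS (-0.20) and DLS (-0.23) and not in NAc (-0.16, adjusted p 0.812), and Ftx, a regulator of Xist, in none without the class term. With the class term the DMS values were -7.32 for Xist, -0.57 for Eif2s3x, -0.40 for Kdm6a and -0.37 for Ddx3x. For Kdm5c, Gm2223 and Pbdc1 they were -0.32, -0.61 and -0.21. Ftx then passed as higher in males (0.32, limma adjusted p 0.0145). In that fit sex stays entangled with the animal number inside the high class.

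Against this direction, the X-linked Rbm3 was higher in males. Its male minus female value was 0.42 ± 0.08 (log2, SE) in NAc, higher in males at 6 of 6 times (adjusted p 0.00191), and 0.40 ± 0.07 in DLS, at 5 of 6 times (0.00036). In DMS it was 0.27 ± 0.08 at 5 of 6 times (0.0833) and 0.30 ± 0.07 with the class term (0.00528). In NAc 9 genes passed in all, 8 higher in females: besides the X-linked genes these were Tiparp, a target of the aryl hydrocarbon receptor (-0.32, 0.0211), and ENSMUSG00000094114, which has no symbol and was named after its values were seen (-0.50, 0.0202). In DLS 23 genes passed, 6 higher in males. Hsd11b1, which regenerates active glucocorticoid, was higher in males (0.41 ± 0.09, 0.0227), as were Serpinb1a (0.35), Pcdhgb1 (0.31) and Tomm20 (0.13, which turned to -0.0066 with libraries scaled to an equal sum); the pseudogenes Pisd-ps1 (-0.64, 6.28e-09) and Pisd-ps2 (-0.55), 5530601H04Rik (-0.41), the kinase Camk1g (-0.31, 0.00576) and the matrix gene Sparc (-0.17, 0.0428) were higher in females. In DMS 110 genes passed, 63 higher in males, and 509 with the class term (270 higher in males), including all 110. Inside the low class alone 41 genes passed, and inside the high class 579. In the high class the libraries of lower numbers were all male. The count with the class term is therefore entangled with the animal number. The count and its direction depend on the fit: a term for the range of animal numbers gave 1995 genes, 887 higher in males and so most higher in females, a replicate block for the animal number 202, and libraries scaled to an equal sum 22. The range term leaves in place the class difference of the 7 high-class libraries of lower numbers, all male. Its count of 1995 is therefore entangled with the class. Dsg1c, of desmosomes, led those higher in males (0.86 ± 0.13, 5.32e-06; 0.83 with the class term), followed by the long RNAs Gm37895, Gm37899, Gm37602 and Mir124a-1hg (0.73, 0.68, 0.66 and 0.59). Higher in females were Clic6 (-0.82, 0.0492), an abundant gene of the choroid plexus, Cd59a (-0.56), Ace (-0.50), Serpinb1b (-0.39), and by small amounts Hsp90ab1 (-0.10) and Atp5d (-0.11); Grm7 (0.15) and Npas2 (0.11) were higher in males. These values became, with the class term, -0.86 for Clic6, -0.56 for Cd59a, -0.52 for Ace, -0.36 for Serpinb1b and 0.16 for Grm7. Limma gave 1301 genes in DMS and 1166 in DLS at an unadjusted p under 0.05.

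**Figure D4:**
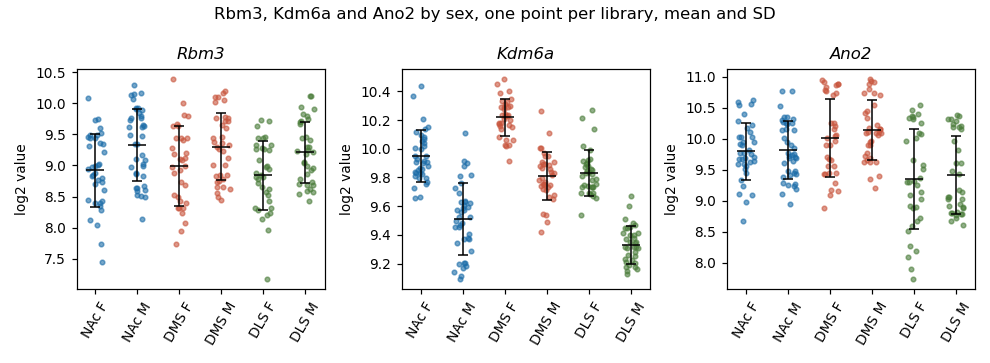
Rbm3, Kdm6a and Ano2 in females and males of NAc, DMS and DLS (log2 normalised count); points are libraries, with their mean and SD. Kdm6a lies higher in females in each region, and Rbm3 averages 8.92 in females and 9.33 in males in NAc and 8.84 and 9.21 in DLS.

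Of the fixed lists, camera placed X-linked genes expressed from the inactive X lower in males in each region, also with an estimated correlation (adjusted p 6.76e-21, 5.53e-15 and 4.58e-24). Calls that also held with it were cold-inducible genes higher in males in NAc (0.000102) and DLS (0.00441), microglia markers higher in males in NAc (0.0412), where astrocyte (0.00262), oligodendrocyte precursor (0.0026) and endothelial and mural markers (0.0203) moved the same way with the preset correlation alone, and collagen and glucocorticoid-responsive genes lower in males in DLS (0.046 each). Red blood cell markers were higher in males in each region with the preset correlation (0.000309, 0.0492 and 0.000306) but not with the estimate (0.221, 0.685 and 0.329), and nor were ribosomal proteins in DLS (6.84e-12; 0.618), oxidative phosphorylation in DMS (4.63e-09; 0.685) or oligodendrocyte markers in NAc (0.000253; 0.447). In all 15 lists passed in NAc, 10 in DMS and 12 in DLS, and 3, 1 and 4 with the estimate. With the class term ribosomal proteins were called higher in males in DMS (3.63e-05 with the preset correlation, 0.757 without the term). Immediate early genes were no longer called (0.0897, against 0.00952 without it). In that fit sex stays entangled with the animal number inside the high class. In every list past the threshold the median and mean shared the sign of the test. Scaling to an equal sum moves male minus female values by -0.14 in DLS, -0.01 in DMS and -0.04 in NAc (log2), which turns the sign of the median of ribosomal proteins in DLS and of no other call named in this paragraph.

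The third question was whether the rhythms of the subregions differ. Ano2 had the clearest difference: its amplitude was 0.37 ± 0.05 (log2, SE, n = 77) in NAc, 0.69 ± 0.05 (n = 70) in DMS and 0.94 ± 0.05 (n = 70) in DLS, and NAc and DLS differed with an adjusted p of 5.99e-09 (4.89e-09 with the class term for DMS). Kcna5 (0.14 ± 0.05 in NAc, 0.56 ± 0.05 in DLS; 5.86e-06) and Ciart (0.75 ± 0.06 and 1.23 ± 0.06; 6.11e-05) were likewise stronger in DLS. Vcan, a matrix proteoglycan of oligodendrocyte precursors (chromosome 13, 89655312 to 89742509), peaked at 22.6 h in DLS (0.38 ± 0.06) and was not rhythmic in NAc (0.13 ± 0.06; 0.000188), and Naa25 (chromosome 5, 121397936 to 121444378) had an amplitude of 0.10 ± 0.03 with a peak at 0.142 h in DLS and was not rhythmic in NAc (0.09 ± 0.02, adjusted p 0.216; difference 0.00132). In all 35 of 11283 shared genes differed between NAc and DLS. Fitted peaks lay over 6 h apart for 15 of them, Vcan and Naa25 included. A fitted peak is poorly defined where a gene was not rhythmic in a region, so the 15 are not a count of shifted peaks. The fitted amplitude was larger in DLS for 30 of the 35 and in NAc for 5, which, named after their values were seen, were Cnih2, Zcwpw1, Mir124-2hg, Sema5b and Mapk3. Among the 30, also named after the fact, were the clock genes Dbp, Bhlhe40, Bhlhe41, Tef and Cipc and the developmental regulator Id4 (0.03 in NAc, 0.28 in DLS). Fitted alone with a weight per region, the pair gave 18 genes, all among the 35.

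Between NAc and DMS 0 genes differed in limma, also with the class term and in the pair fitted alone, and 2569 had an unadjusted p under 0.05 (1287 with the class term), where the joint fit gave 789 in data simulated without a difference. The pair fitted alone gave 1659 (1050 with the class term; 564 are due by chance). This 0 was unstable, since leaving out single animals gave up to 543 genes. Between DMS and DLS 0 genes differed in the same fits. Here 1043 genes had an unadjusted p under 0.05 in the joint fit, and 2024 in the pair fitted alone, or 549 with the class term, against 564 due. The joint fit was too strict for this pair in simulated data.

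Where a gene was rhythmic in both regions of a pair, its peaks mostly lay close together. NAc and DMS shared 254 rhythmic genes (156.7 are expected of independent lists), NAc and DLS 222 (62.3) and DMS and DLS 1783 (1248.5), and 212 were rhythmic in all 3. The median peak difference was 1.09 h (95% interval 0.91 to 1.62) for NAc and DMS and 0.89 h (0.89 to 1.30) for NAc and DLS. For DMS and DLS it was 1.17 h (1.11 to 1.74). Resampling animals adds noise to absolute differences, so these intervals lean towards larger values. Peaks lay within 4 h for 96.9%, 97.7% and 95.8% of these genes. With the class term the 238 genes shared by NAc and DMS had a median of 0.92 h, with 98.3% within 4 h, and the 1473 shared by DMS and DLS 0.98 h, with 98.9%.

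The clock as a group was weakest in NAc and strongest in DLS. Over 20 core clock and output genes the mean amplitude was 0.25 in NAc and 0.34 in DMS for 63 animals with both (difference -0.08, log2), 0.25 in NAc and 0.42 in DLS for 57 (-0.17), and 0.34 in DMS and 0.43 in DLS for 51 (-0.09). Each two-sided permutation p was 1e-04, the smallest that 10000 resamples can give (adjusted p 1e-04 over the 3 pairs). With the class term the differences that involve DMS were -0.10 and -0.07, and with core clock genes alone the 3 differences were -0.07, -0.16 and -0.09. The NAc values carry the adjustment that no label records, so a difference that involves NAc rests on tables made in unlike ways.

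**Figure D5:**
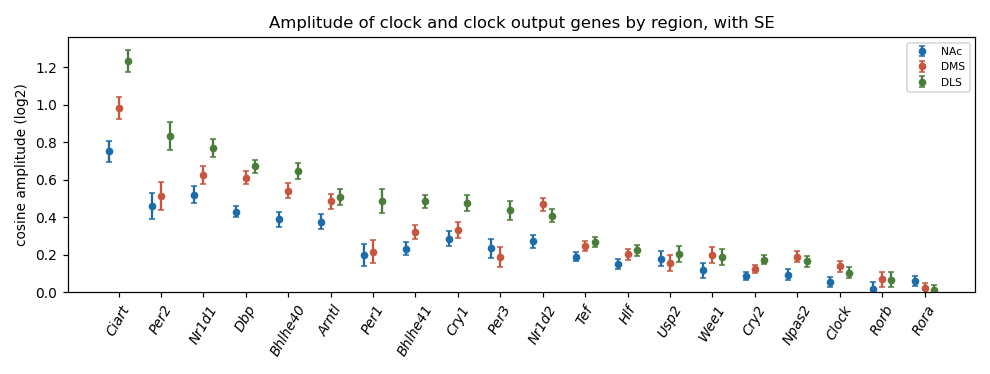
Amplitude (log2) of the 20 core clock and clock output genes in NAc, DMS and DLS; points are fitted amplitudes and bars their SE. Ciart spans 0.75 in NAc to 1.23 in DLS.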

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

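Tests chosen only after the result was seen were those of the DMS library classes, the reading of the clock amplitudes as a cause of the NAc count, and every DMS value with the class term. The test of amplitude over all shared genes was also chosen after the data were seen, though before its own result. The tests of added spread and of removed number ranges in DLS were set before their result was seen.

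Single libraries lay far from the others of their sex and time in the share of mitochondrial rRNA. In DMS these were female ZT22 number 49 (40.78%, the other 5 at 21.2 to 24.9%), male ZT2 number 31 (42.58%, others 22.3 to 25.3%) and male ZT22 number 47 (44.08%, others 19.8 to 25.3%); in DLS they were male ZT2 number 10 (47.88%, others 38.5 to 41.3%) and male ZT6 number 13 (13.17%, others 39.04 to 49.7%). In the share of the rRNA-like genes Gm42418 and Gm26917, DLS male ZT6 number 13 held 68.4% (others 1.43 to 2.05%), DLS male ZT18 number 46 3.89% (1.36 to 2.09%), DMS female ZT18 number 45 5.01% (1.08 to 1.76%), DMS female ZT10 number 37 1.86% (1.39 to 1.46%) and NAc female ZT18 number 47 3.04% (2.32 to 2.47%). Of 72 combinations of group and measure 10 stood out, where chance gives about 1 in 20. Without DLS male ZT6 number 13 there were 2398 rhythmic DLS genes, 2133 in females, 456 in males and 19 genes with a sex difference of level, and 0 with a sex difference of rhythm.

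The 3 DMS libraries come from animals numbered 31 or higher and belong to the high class of mitochondrial rRNA, and the classes bear on the peaks of rhythmic genes in DMS, which bunched from 0 to 4 h and from 12 to 16 h (32.5% and 31.3%) without the class term. Of the genes in these windows 91.6% differed between the classes at the same time of day in the direction that the uneven spread of classes over the day needs, where 78.5% of all genes differed in either direction. A daily rhythm that bunches the peaks inside each class is argued against, since only 33.2% of genes rhythmic inside the low class and 16.3% inside the high class peaked there. Library classes that follow the time of day of the animals are argued against as the whole cause, since 0 of the 26 libraries of animals numbered 31 or higher were of the low class at any of the 6 times, and 37 of the 44 of lower numbers were. The bunching may therefore come from classes that go with the animal numbers. The origin of the classes stays open. So does why 7 libraries of lower numbers, all male and 4 of them at ZT18, were of the high class.

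The rhythm differed between NAc and DLS for named genes in the test of the difference itself: Ano2 (adjusted p 5.99e-09), Kcna5 (5.86e-06), Ciart (6.11e-05), Vcan (0.000188) and Naa25 (0.00132). The mean clock amplitude also differed between each pair of regions, by -0.0815 (NAc minus DMS), -0.1703 (NAc minus DLS) and -0.0889 (DMS minus DLS, log2). The clock amplitude was thus smallest in NAc, which also had the fewest rhythmic genes, 304 against 2392 in DLS. With libraries scaled to an equal sum these counts were 108 and 216, a much smaller gap. That scaling moves every value of DLS male ZT6 number 13 by -2.43 (log2), which widens the DLS spread. No equal-sum fit without this library was run, so how far the gap depends on the scaling is not known. For rhythmic genes at large the order varied: the larger amplitude was in NAc for 57.7% of the 222 genes rhythmic in both NAc and DLS and for 43.3% of the 254 rhythmic in both NAc and DMS. The median amplitude of rhythmic genes was 0.198 in NAc, 0.151 in DMS and 0.125 in DLS. Passing in a noisier table selects for large fitted amplitudes, so these values lean towards NAc and do not rank the regions.

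The residual SD was 0.31 in NAc and 0.20 in DLS. DLS values with noise added up to the NAc spread gave a median of 756 rhythmic genes over 20 draws (685 to 791), still more than 1.5 times the NAc count. The added noise was independent between genes, so this argues only against independent spread as the whole cause of the lower count. It does not test a spread that the genes of a library share. In NAc array weights gave 661 rhythmic genes and the mitochondrial rRNA share as a covariate 508. Removing the mean difference between ranges of animal numbers in DLS left 2610 rhythmic genes. The median size of that difference was 0.0666 (log2) in DLS, and its size in NAc before the adjustment is unknown. This therefore does not decide whether such a removal lowered the NAc count. Smaller amplitudes hold for the clock genes (-0.17), which are too few to make up the count; over all 11289 genes shared by NAc and DLS the mean squared amplitude less its sampling variance differed by -0.00215 ± 0.00295 (NAc minus DLS, jackknife SE), which decides nothing. A spread shared by the genes of a NAc library, the unrecorded adjustment of the NAc values, which could have shrunk them, and a difference between the tissues themselves stay open.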

How the results depend on the processing

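Alternatives listed as class term, mitochondrial rRNA share, voom and pairs fitted alone were chosen after the data were seen; the others were set before the data were examined.

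Clock amplitude differences between regions kept their direction and p of 1e-04 under each alternative run (quantile normalisation, number range, core clock alone, all libraries, class term), at -0.0653 to -0.0952 for NAc and DMS, -0.1566 to -0.1703 for NAc and DLS and -0.0748 to -0.0889 for DMS and DLS; without single animals they were -0.0864 to -0.075, -0.1764 to -0.1624 and -0.092 to -0.0857. Counts of rhythmic genes stayed within 1.5 times under quantile normalisation, a pseudocount of 8, a mean log2 of at least 6, robust fits and no sex term, and under voom in DMS and DLS.

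Libraries scaled to an equal sum gave 108 rhythmic genes in NAc, 9320 in DMS and 216 in DLS, and 22 and 12 genes with a sex difference of level in DMS and DLS; by construction this adds the changing rRNA share to every gene. It moved the peak of DMS genes by over 6 h, with amplitudes of 0.0596 for Cry2, 0.00721 for Herpud1, 0.111 for Chrm4, 0.056 for Gpr6, 0.0387 for Grik5, 0.104 for Gabrb2, 0.0532 for Fdft1, 0.0703 for Aldoc, 0.0511 for Ctss, 0.0886 for Itgam and 0.0412 for Eif2s3x, and turned Tomm20 in DLS to -0.0066 (male minus female). Of the named amplitudes 15 of 47 in NAc, 8 of 102 in DMS and 49 of 90 in DLS fell below the threshold under it.

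The class term gave 3051 rhythmic genes in DMS and 509 with a sex difference, a count entangled with the animal number inside the high class. Peaks moved by over 6 h for Mki67 (amplitude 0.20), Ankrd11 (0.0153), Sst (0.0404) and Npy (0.028). Besides these 4 genes, 20 of 102 named amplitudes were no longer past the threshold. Ribosomal proteins turned from higher to lower in the dark (camera adjusted p 0.0128). With the mitochondrial rRNA share as a covariate NAc had 508 rhythmic genes and 330 with a sex difference, and DMS 3459 and 980; peaks in DMS moved for Mki67 (0.47), E330034L11Rik (0.30), Ankrd11 (0.16), Grik3 (0.0547), Gpr6 (0.0773), Nos1 (0.0317), Lhx6 (0.0396), mt-Nd1 (0.0137), mt-Nd2 (0.0463), mt-Nd3 (0.0933), Eif2s3x (0.0246), Sst (0.109) and Npy (0.0792). A term for the range of animal numbers gave DMS 3772 rhythmic genes, 1172 in females, 2961 in males and 1995 with a sex difference, and turned the Naa25 amplitude difference of NAc and DLS to 0.0014. In DMS this term leaves in place the class difference of the 7 high-class libraries of lower numbers, all male. The cause was not tested beyond the classes.

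Array weights gave 661 rhythmic genes in NAc and 9340 in DMS and 700 and 37 genes with a sex difference in DMS and DLS; the cause was not tested. A replicate block for the animal numbers gave 202 genes with a sex difference in DMS, with rhythmic genes at 323, 4358 and 2044 in NAc, DMS and DLS, 9 and 31 sex differences in NAc and DLS, and 0 sex differences of rhythm. An adjusted p under 0.01 gave 118, 3449 and 1337 rhythmic genes, as a stricter threshold must. An unadjusted p under 0.01 gave 753 rhythmic genes in NAc, 85, 87 and 331 sex differences of rhythm, 145, 530 and 322 of level, and 854, 335 and 204 region differences (NAc and DMS, NAc and DLS, DMS and DLS).

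Time as 6 levels gave 183 rhythmic genes in NAc, and 1 and 19 region differences (NAc and DMS, NAc and DLS); sex by time as 6 levels gave 1 gene in NAc and 13 in DLS; the cause was not tested. The single genes, named after their values were seen, were Larp4 (NAc and DMS, adjusted p 0.0416) and Ephb6 (sex by time in NAc, 0.0176). Fitting a sex alone, with fewer libraries, gave 53 genes in NAc females, 776 in DMS males and 1308 in DLS females. Leaving out ZT6, ZT10, ZT14 or ZT18 gave 130, 151, 131 and 119 rhythmic genes in NAc, and leaving out ZT14 1408 in DLS, with fewer libraries and times.

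Quantile normalisation gave 13 and a pseudocount of 8 gave 14 region differences between NAc and DMS, and the cause was not tested. Paired differences of animals with both regions, a replicate block with fewer libraries, gave 14 for NAc and DLS. The pair fitted alone gave 18, with or without the class term. Peaks compared between different animals, with fewer libraries, differed by 1.35 and 1.61 h for NAc and DMS, 1.29 and 1.32 h for NAc and DLS and 1.60 and 1.58 h for DMS and DLS; with the class term DMS and DLS differed by 0.98 h. With a correlation estimated per list, 2, 1 and 0 lists passed for dark minus light in NAc, DMS and DLS and 3, 1 and 4 for male minus female, and with quantile normalisation 5 passed for dark minus light in DMS.

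Without single libraries, rhythmic genes ranged from 260 to 390 in NAc, 5433 to 6834 in DMS and 2235 to 2603 in DLS; in females 65 to 120, 1323 to 4063 and 1521 to 2341; in males 18 to 46, 820 to 2063 and 412 to 566; sex differences of level 9 to 11, 84 to 168 and 18 to 37; and sex differences of rhythm 0 to 0. The libraries that moved a count by over 1.5 times were, for NAc males, male ZT6 number 13 (23), ZT14 number 21 (21) and ZT2 number 32 (18). For DMS females they were female ZT14 number 25 (3459) and number 43 (1323) and ZT2 number 31 (3664) and number 33 (4063), and for DMS males male ZT2 number 31 (2063), ZT6 number 34 (1972) and ZT22 number 47 (1830). For the sex difference of level they were DMS male ZT22 number 2 (168) and DLS male ZT10 number 38 (37). Leaving out 1 animal gave 23 to 43 region differences for NAc and DLS (23 without F4), 0 to 0 for DMS and DLS and 0 to 543 for NAc and DMS, with 1 or more in 40 of 93: M47 (543), F49 (186), F18 (59), M21 (48), M16 (38), F2 (38), M23 (22), F7 (19), M13 (18), F20 (18), F31 (18), F33 (17), M31 (17), F46 (16), F28 (15), F44 (14), F21 (13), M43 (11), M2 (11), F25 (10), F53 (10), M22 (9), F10 (8), F11 (8), M15 (8), F27 (7), F29 (7), F14 (5), F52 (5), M17 (5), M29 (5), F12 (4), F1 (4), F47 (4), M28 (4), M35 (4), F15 (4), F24 (3), M44 (2), F5 (1).

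Sequencing depth is unknown in NAc, so what it limits there was not tested. In DMS and DLS the recovered reads gave the same side of the threshold in voom for 101 of 102 and 89 of 90 named amplitudes.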

Other observations

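Tests chosen only after the result was seen were the splits of the libraries, the class term and the test of scaling on Rbm3. The test of Rbm3 against chaperones was set before its result was seen.

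Rbm3 was higher in males in NAc and DLS, and a scaling difference between the sexes as the whole cause is argued against: with libraries scaled to an equal sum the male minus female value was 0.38 in NAc and 0.27 in DLS (log2), though the DLS call was then lost, and the shift of -0.14 in DLS comes in part from male ZT6 number 13, whose values move by -2.43. Since Rbm3 is induced by cooling and chaperones by heat, a lower tissue temperature in males is a candidate explanation. Over libraries of the same sex and time, Rbm3 fell where the mean of the heat shock chaperones rose, with Pearson r -0.32 in NAc (two-sided permutation p 0.00443 and adjusted p 0.00443; Spearman rho -0.355, p 0.00182; r -0.378 without the 2 farthest libraries; n = 77) and -0.418 in DLS (p 0.00047, adjusted p 0.00094; rho -0.396, p 0.00083; r -0.321 without the 2 farthest; n = 70); these are the 2 relations computed. Both fit the hypothesis, but they were taken over what is left after sex, time and number range are removed, so they do not show that temperature differs between males and females. The chaperones were lower in males in NAc, DMS and DLS in camera with the preset correlation (adjusted p 0.000593, 0.000359 and 0.0452) but not past the threshold with an estimated one (0.221, 0.161 and 0.618), and sex hormones and the dose of X-linked genes stay open.

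Single glial and vascular genes cycled in more than 1 region, while the lists of astrocyte (adjusted p 0.221, 0.86 and 0.795 in NAc, DMS and DLS, Fisher's exact test) and oligodendrocyte markers (0.75, 0.86 and 0.795) held no excess of rhythmic members without the class term. Opalin, a myelin protein of oligodendrocytes, peaked in the early light phase with folds of 1.61 in NAc (adjusted p 0.00625), 1.78 in DMS (8.46e-08; 1.72 with the class term) and 1.55 in DLS (1.96e-05). The astrocyte genes Gjb6 (folds 1.53, 1.5 and 1.45; 1.33 in DMS with the class term) and Fgfr3 (1.22, 1.25 and 1.24; 1.23 with the class term) peaked in the dark. The collagen gene Col4a1 of the vessel wall had 1.93-fold in DMS (1.46 with the class term) and 1.59-fold in DLS (6.83e-06), with peaks at 2.30 and 2.12 h. The receptor Kdr of endothelial cells had 1.49-fold in DMS (1.47 with the class term) and 1.64-fold in DLS (3.25e-08), with peaks about lights on. In DLS the striatal marker Coch had 1.61-fold (peak 3.14 h, 3.42e-12) and Fst 1.57-fold (17.4 h). Among X-linked genes Ddx3x was rhythmic in each region (folds 1.19, 1.12 and 1.14), in DMS without the class term only (0.139 with it).

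Genes with a sex difference of level rose to 330 in NAc when the mitochondrial rRNA share was a covariate, against 9 without it, and rhythmic genes to 508 against 304. The lowest male share in NAc was 26.06% (ZT22 number 3), and the libraries below it (22.69 to 25.13%) were all female. These were numbers 2, 7, 9, 11, 12, 17, 19 and 48. The share is thus partly entangled with sex in NAc, and the counts with the covariate depend on that. This structure of the NAc libraries could hide differences, and its origin was not tested.

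Each result was set against 100 splits of the libraries, the real one included, without correction over the results. The number of splits as large was 1 for rhythmic genes in NAc (304, highest other 4), 2 in NAc females (85, highest other 1001) and 1 in NAc males (35, 4). It was 1 in DMS (6207, 3151), 1 in DMS females (2164, 88), 2 in DMS males (1201, 1357) and 1 in DMS with the class term (3051, 24). In DLS it was 1 for all libraries (2392, 21), for females (2028, 1273) and for males (501, 0). For the sex difference of level it was 3 in NAc (9, 973), 2 in DMS (110, 5166) and 1 in DLS (23, 1). Swaps of regions within animals gave 2 for NAc and DLS (35, 1162). So few splits cannot exclude chance, and only the splits for DMS with the class term kept the DMS class. Results of 0 genes cannot be set against chance in this way, since all 100 splits give 0 or more: these were the sex difference of rhythm in NAc (highest other 1246), DMS (1) and DLS (0), and the rhythm difference of NAc and DMS (1822) and of DMS and DLS (0). Splits with several times the real count, such as 1001, 973 and 1246 in NAc, 5166 in DMS and 1822 and 1162 between regions, point to a structure of the samples besides the groups; in DMS the class term brought the highest other count from 3151 to 24.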
